A study of Mus musculus with 20 samples.

How the data were processed

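RNA from mouse liver was measured in 20 libraries, 10 of them input libraries by their titles and 10 without that word, which were taken as the m6A pull-down libraries of the same assay. The deposited table holds read counts per RefSeq transcript for the input libraries, unnormalised, in the unit counts. The deposited table also holds TPM per transcript, per the file headers, and each TPM column sums to 1000000. The TPM were used only for that check. Per the labels, the authors used bcl2fastq, TopHat2 2.0.13 and MACS2 2.1.0.20151222, and genome builds hg19, mm10 and rn6 are named without their roles. The read counter, the strand setting and the annotation release are not given in the sources used here, and the coordinates look like mm10.

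The table has 79884 transcripts of 21769 genes, of which 13250 have more than 1 transcript. Isoforms share reads: of 8618 such genes with at least 100 reads, 77.1% have a second transcript with over 90% of the count of the first. Each gene was therefore given the count of its transcript with the highest sum over the 10 libraries, and sums over transcripts, 2.7 to 2.9 times as large in total, were an alternative. Totals were 11354034 to 25860245 over transcripts, and 12730 to 16519 genes were detected per library. The table also has 12 columns, of 6 libraries, that match no sample, and these were not used. The pull-down libraries and peaks were not analysed here, so the planned comparisons of m6A enrichment and of peaks were not run.

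The input libraries formed 4 groups by exposure and time, with 2 controls and 3 exposed livers at each of 3 and 9 months. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Counts were filtered with filterByExpr, which left 14067 genes, scaled by TMM, and fitted with edgeR's quasi-likelihood model over all 10 libraries (common dispersion 0.309, prior degrees of freedom 7.6, residual degrees of freedom 6). The contrasts were cadmium against control at 3 and at 9 months, the difference of these effects, and 9 against 3 months within controls and within exposed livers. All tests were two-sided, with a threshold of 0.05 on the Benjamini-Hochberg adjusted p. CPM are given as mean and SD over the libraries of a group, and log2 fold changes with the SE of the edgeR fit. DESeq2 gave no adjusted p for 1127, 36, 855, 1127 and 2218 genes in the 5 comparisons, in that order.

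The 34 gene lists hold 589 symbols, of which 556 were matched, 4 of them through the reference annotation. They cover metal handling, NRF2 and glutathione, m6A machinery, fatty acid and triglyceride synthesis, fat uptake and lipid droplets, PPARA targets and fatty acid oxidation, cholesterol synthesis, bile acid synthesis and transport, xenobiotic P450 and regulators, glucose metabolism, ER stress and integrated stress response, heat shock, p53 targets and apoptosis, and cell cycle. They further cover acute phase, cytokines and chemokines, interferon response, extracellular matrix and stellate cells, autophagy, circadian clock, immediate early, male-biased and female-biased liver genes, Y-linked genes and Xist, and mitochondrially encoded mRNAs. The rest are markers of hepatocytes, Kupffer cells and macrophages, lymphocytes, neutrophils, endothelium, cholangiocytes, erythroid cells, pancreas and adipose tissue. Lists with at least 3 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with an estimated correlation and fry as alternatives. Camera compares a list with other genes, and fry tests whether its members move, on balance, one way.

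The groups, comparisons, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. The rule names the m6A machinery genes, Mt1 and Mt2 in every comparison. It adds the 5 genes per direction with the largest fold change among those past the threshold whose groups do not overlap and whose mean is at least 1 CPM. From each list it takes up to 4 members past the threshold, or the 2 with the highest level where none passed. The fixed alternatives were DESeq2, its size factors in edgeR, no filter on low counts, a filter of at least 5 CPM in 2 libraries, an adjusted p under 0.1, the libraries of a time alone, the replicate number as a block, and leaving out each library. Added after the data were seen were the list tests of the difference and of time, leaving out each library for the lists, sums over transcripts, limma voom with library weights, and fits without the 2 libraries with the most pancreas-list RNA or without both 3-month controls.

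For genes with 0 counts in a group, the fold was computed against a floor of 3 counts per library and written as a lower bound. For genes with 1 to 3 counts the ratio has an exact 95% interval for counting error. The clock score used log2 CPM with a pseudocount of 1 and compared arms by rearranging libraries within times. The steps were tested on simulated data with 50 changed genes per fold. edgeR recovered 66% of genes changed 4-fold in each comparison with cadmium, 38% between the control groups and 74% between the exposed groups, and 94%, 84%, 92% and 92% of genes changed 8-fold. Of its 126 to 145 calls per comparison 8 to 13 were false, against 36 to 43 of 170 to 189 for DESeq2. The simulation gave each gene the same dispersion in all groups and changed only genes above a set mean CPM. The real 3-month controls varied more (biological coefficient of variation 0.91, against 0.37 to 0.53 in the other groups). These rates may therefore not hold for comparisons with those controls or for genes with few counts.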

Results

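Livers of wild-type mice given cadmium chloride (CdCl2, 100 mg/L in drinking water) for 3 or 9 months were profiled beside control livers by m6A sequencing. In this assay, RNA fragments that carry m6A, a methylated adenosine, are pulled down with an antibody and sequenced beside an input library made without the pull-down. The values used here are counts per transcript in the 10 input libraries, which measure RNA abundance. They comprise 2 control and 3 exposed livers at 3 months, and 2 control and 3 exposed livers at 9 months. The 10 pull-down libraries and m6A peaks were not analysed here. The count over genes was 5465073 and 8912898 in 3-month controls 2 and 3, and 3958171 and 7460923 in 9-month controls 1 and 2. It was 6962244, 7336763 and 7697203 in exposed livers 1 to 3 at 3 months, and 6054493, 6546991 and 4545353 at 9 months. A floor of 3 counts per library corresponded to 0.34 to 0.76 CPM (counts scaled to a library total of 1000000), and floors and intervals cover counting error only. The labels do not say whether the replicates of a group were separate animals, so each p measures only the spread between these samples. That spread was pooled for each gene over the groups of the fit.

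The 2 controls at 3 months stood apart from the other libraries. Their log2 CPM correlated with each other at r = 0.775 across 8226 genes, which are not independent replicates, and their median r with the other libraries was 0.823 and 0.809, against 0.885 to 0.93 for the rest. The biological coefficient of variation was 0.91 between them and 0.37, 0.53 and 0.46 within the 9-month controls and the exposed livers at 3 and 9 months. With a spread pooled over these groups, p values may be too small in comparisons with the 3-month controls and too large in the others. Transcripts of pancreatic digestive enzymes were abundant in some libraries. The 11 pancreas-list genes summed to 9800 CPM in 9-month control 2, 1900 CPM in 9-month exposed liver 1 and 257 CPM in 3-month control 3, against 8.55 to 33.7 CPM in the other libraries.

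**Figure D1:**
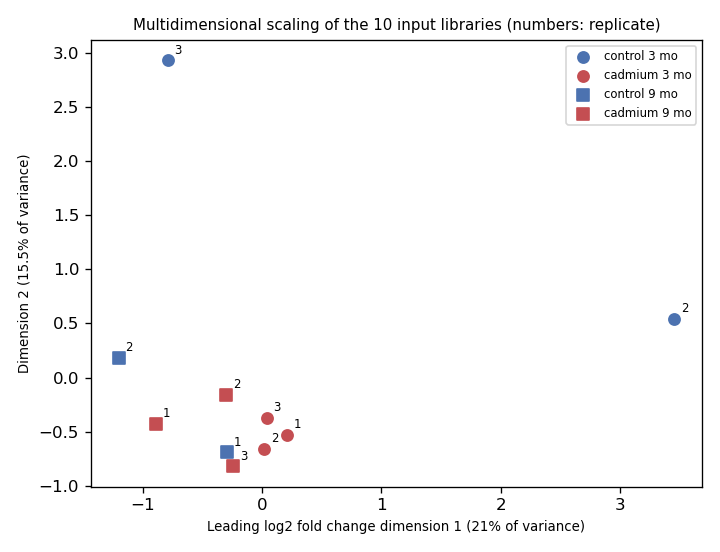
Multidimensional scaling of the 10 input libraries, with leading log2 fold change dimension 1 (21% of variance) on the x axis and dimension 2 (15.5%) on the y axis, coloured by exposure and shaped by time, each point a library with its replicate number. The 3-month controls lie farthest out, at 3.45 on dimension 1 (replicate 2) and 2.93 on dimension 2 (replicate 3).

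The first comparison asks which liver transcripts differ after 3 months of cadmium, in 3 exposed and 2 control livers. Genes of the circadian clock made up 3 of the 7 genes that changed. Per3, a period gene of the clock, had 1 count over both control libraries and 952 over the exposed ones, a ratio of 584 after scaling for depth (exact 95% counting interval 105 to 23100). Dbp, a transcription factor gene driven by the clock, had 1 and 435 counts, a ratio of 267 (47.6 to 10600). Tef, a relative of Dbp, rose by 2.77 ± 0.44 on the log2 scale (SE), from 26.3 ± 3.87 CPM (SD, n = 2) to 181 ± 103 CPM (SD, n = 3). Gstt2, which encodes a glutathione S-transferase, rose by 2.33 ± 0.35 from 19.2 ± 1.14 to 96.8 ± 16.2 CPM, and Galk1, which encodes galactokinase, rose by 2.20 ± 0.33 from 10.7 ± 2.41 to 49.2 ± 8.84 CPM. Igfbp1, whose product binds insulin-like growth factors, fell by 6.08 ± 0.87, with 176 and 2116 CPM in the controls and a mean of 16.9 ± 4.45 CPM in exposed livers. Rnf125, a ubiquitin ligase gene, fell by 2.55 ± 0.31, from 2116 ± 710 to 362 ± 13.8 CPM. For each of these 7 genes all 3 exposed livers lay beyond both controls.

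In edgeR, 7 of 14067 genes passed an adjusted p of 0.05 at 3 months, 5 higher and 2 lower, and 2042 had an unadjusted p under 0.05. The adjusted p was 0.00643 for Per3, Dbp and Rnf125, 0.026 for Igfbp1, 0.0294 for Galk1, 0.0328 for Gstt2 and 0.0477 for Tef. By the table's coordinates, which look like mouse build mm10, Per3 (gene ID 18628) lies on chromosome 4 from 151003657 to 151044713, Dbp (13170) on chromosome 7 from 45705247 to 45710203 and Tef (21685) on chromosome 15 from 81811229 to 81826863. Gstt2 (14872) lies on chromosome 10 from 75831842 to 75834965, Galk1 (14635) on chromosome 11 from 116008357 to 116012719, Igfbp1 (16006) on chromosome 11 from 7197787 to 7202546 and Rnf125 (67664) on chromosome 18 from 20961126 to 20987359. Per3 and Dbp stayed past the threshold with each of the 10 libraries left out, while Tef and Galk1 did so in 5, Gstt2 and Igfbp1 in 6 and Rnf125 in 7 of the 10. The count was 720 without 3-month control 2, 1247 without 3-month control 3, 3 without exposed liver 1, 2 or 3 of that time, and 3 without 9-month exposed liver 1. It was 479 with DESeq2, 502 without the low-count filter and 11 with counts summed over transcripts. With limma voom and library weights it was 2, both lower, so Per3, Dbp and Tef did not pass there. It was 0 when the 5 libraries of that time were fitted alone (smallest adjusted p 0.265). Over the alternatives, the adjusted p of Per3 reached 0.817 and that of Dbp 0.742. Where a control is left out, the lone control of its time is assumed to vary like the other groups. Groups did not overlap for 25.8% of genes, where chance gives 20%.

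Across the circadian clock list, 14 of 18 measured genes were higher in exposed livers at 3 months (median log2 fold change 0.94, also 0.94 with Ciart at its bound). Over all genes 3 passed, and adjusted over the list alone 6 were higher and 3 lower. Members named here and below because they passed only over their list alone were chosen after their values were seen. The 6 were Per3, Dbp, Tef, Nr1d1, Nr1d2 and Ciart, and the 3 were Arntl, Nfil3 and Clock. Nr1d1 and Nr1d2 encode the REV-ERB repressors of the clock and had log2 fold changes of 1.81 ± 0.51 and 1.06 ± 0.32 (adjusted p over all genes 0.146 and 0.17). Ciart had 0 counts in both controls and was at least 9.76-fold higher (floor of 3 counts per library). Arntl and Clock, the activators of the molecular clock, had log2 fold changes of -3.77 ± 0.83 and -1.03 ± 0.38, and Nfil3, a repressor that opposes Dbp, had -3.17 ± 0.58 (adjusted p over all genes 0.0859, 0.26 and 0.073). The list rose as a set by camera (adjusted p = 0.012), with adjusted p = 0.625 with an estimated correlation, and the call was lost without 3-month control 2 and without 3-month control 3.

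Of the other lists, 6 passed camera at 3 months. The acute phase list, plasma proteins that the liver secretes in inflammation, fell as a set (median -1.05, 6 of 20 higher, adjusted p = 0.00293, adjusted p = 0.625 with an estimated correlation). Adjusted over the list alone 6 of its genes were lower, Orm1, Fga, Fgb, Fgg, Itih3 and Serpina3m, and over all genes 0 passed in edgeR, as for the fibrinogen gene Fgg at -1.55 ± 0.30 (adjusted p = 0.0822). The p53 and apoptosis list fell (median -0.67, 4 of 18 higher, adjusted p = 0.0144, adjusted p = 0.591 with an estimated correlation). Of its genes 0 passed over all genes in edgeR and 3 were lower adjusted over the list alone, the cell cycle inhibitor gene Cdkn1a (-4.48 ± 0.90), Trp53inp1 (-2.38 ± 0.47) and Sesn1 (-2.34 ± 0.56). The cholesterol synthesis list rose (median 0.90, 17 of 23 higher, adjusted p = 0.0256) and so did the list of PPARA targets and fatty acid oxidation (median 0.66, 21 of 25 higher, adjusted p = 0.0239), each with adjusted p = 0.747 with an estimated correlation. Over all genes 0 of their members passed, and adjusted over the list alone 0 cholesterol genes passed, while Hadha, a subunit of mitochondrial fatty acid oxidation, was higher (1.10 ± 0.29) and Pdk4, a kinase that limits glucose oxidation, lower (-2.49 ± 0.69). The interferon response list rose (median 0.52, or 0.42 with 2 genes at their bounds, 12 of 18 higher, adjusted p = 0.0444, adjusted p = 0.625 with an estimated correlation), with Irf9 past the threshold adjusted over the list alone (1.52 ± 0.38) and 0 genes past it over all genes.

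The pancreas list fell at 3 months (median -6.50, also -6.50 with Try4 at its bound, 0 of 11 higher, adjusted p = 0.00293, adjusted p = 0.734 with an estimated correlation), beside the 257 CPM of its genes in 3-month control 3. None of its members passed over all genes or adjusted over the list alone in edgeR. Without 3-month control 3 all 7 list calls of this time were lost, and the smallest adjusted p was 0.534. The call of PPARA targets was also lost without 3-month exposed liver 1, that of cholesterol synthesis without 3-month exposed liver 3, and that of the interferon list without 3-month exposed livers 1 or 2 or 9-month exposed livers 1 or 3. With fry 0 of the lists passed (smallest adjusted p 0.306).

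The glucose metabolism list did not pass camera at 3 months (median -0.28, 6 of 16 higher, adjusted p = 0.212), and its members went both ways. Over all genes Igfbp1 fell, and adjusted over the list alone 5 genes were lower. Pklr, the liver pyruvate kinase gene (1.62 ± 0.41), and Gys2, the liver glycogen synthase gene (1.27 ± 0.36), were higher over the list alone. The lower ones were Igfbp1, G6pc, the glucose-6-phosphatase gene (-2.36 ± 0.40), Tat (-2.21 ± 0.65), Ppargc1a (-1.54 ± 0.53) and Foxo1 (-1.11 ± 0.35). The adjusted p over all genes of the 5 lower genes ran from 0.026 for Igfbp1 through 0.0682 for G6pc to 0.229 for Ppargc1a.

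The metallothioneins Mt1 and Mt2, small proteins that bind cadmium and zinc, did not pass the edgeR test at either time. At 3 months their log2 fold changes were -2.59 ± 0.95 and -3.29 ± 1.28 (adjusted p = 0.251 and 0.275 in edgeR), and without 3-month control 3 they were 1.67 and 4.35, so their direction rests on that library. Without 3-month control 2 they were -3.54 and -4.28 and passed the threshold (adjusted p = 0.00151 and 0.00241). Without the low-count filter the same folds passed (adjusted p = 5.79e-12 and 6.89e-17), as the standard errors fell to 0.33 and 0.36. Mt1 read 32 and 1193 CPM in 3-month controls 2 and 3, 119, 56.9 and 130 CPM in the exposed livers of 3 months, 42.5 and 104 CPM in the 9-month controls and 56.2, 196 and 49.4 CPM in the exposed livers of 9 months. At 9 months the log2 fold changes were 0.45 ± 0.96 for Mt1 and 0.58 ± 1.30 for Mt2. The metal handling list did not pass camera (median -0.24 at 3 months, adjusted p = 0.253, and -0.01 at 9 months, adjusted p = 0.23). Adjusted over the list alone, 1 of its genes was higher at 3 months, the ferritin light chain gene Ftl1 (1.39 ± 0.39), and 2 were lower, the transferrin receptor gene Tfrc (-1.38 ± 0.36) and the metal transporter gene Slc39a14 (-1.84 ± 0.55), with 0 over all genes in edgeR and 0 at 9 months.

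Mettl3, the catalytic subunit of the m6A writer named in the study's title, had log2 fold changes of -0.23 ± 0.63 at 3 months (adjusted p = 0.906) and -0.17 ± 0.63 at 9 months (adjusted p = 1.0), from 10 ± 5.53 to 8.47 ± 3.99 CPM and from 8 ± 3.07 to 7.09 ± 1.20 CPM. Its sign at 3 months changed between settings, from -0.71 to 0.48. Mettl14, its partner in the writer complex, had log2 fold changes of 3.13 ± 1.37 (adjusted p = 0.322), from 0.352 to 3.56 CPM, and -0.24 ± 1.14. The 19 measured genes of the m6A machinery list had medians of -0.25 at 3 months and 0.09 at 9 months, and the list did not pass camera (adjusted p = 0.252 and 0.506). None of them passed the threshold in edgeR over all genes or adjusted over the list alone at either time, and 3 and 1 had an unadjusted p under 0.05.

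**Figure D2:**
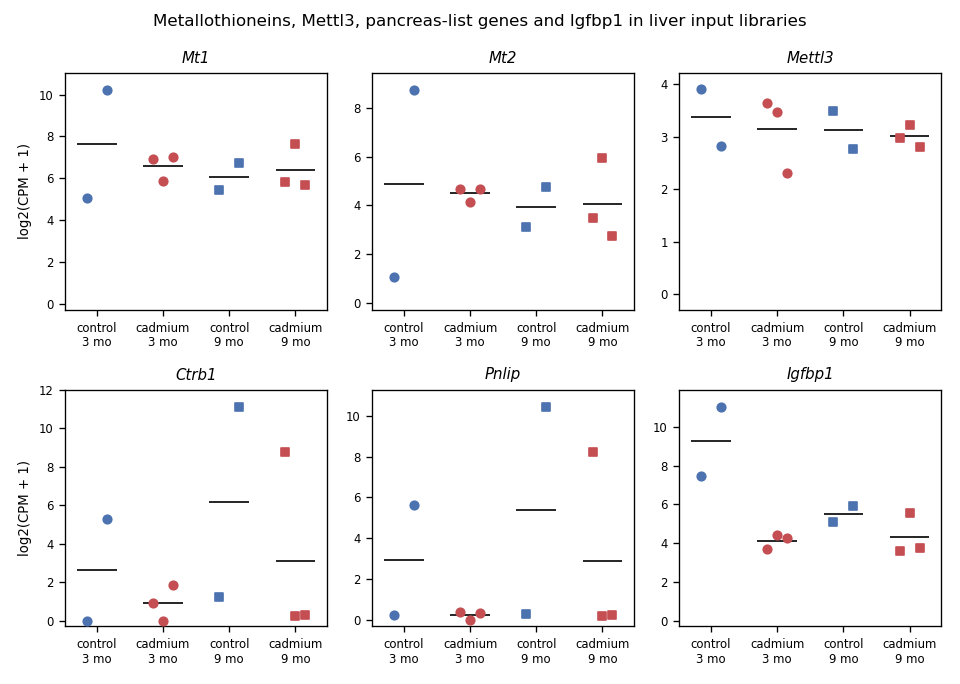
Abundance as log2(CPM + 1) of Mt1, Mt2, Mettl3, the pancreas-list genes Ctrb1 and Pnlip, and Igfbp1 on the y axes, in the control (blue) and exposed (red) livers of each time, each point a library and each line a group mean. Mt1 is highest in a 3-month control at 1193 CPM, and Igfbp1 lies at 176 and 2116 CPM in the 3-month controls.

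The second comparison asks the same question after 9 months, in 3 exposed and 2 control livers. Dbp had a log2 fold change of 4.21 ± 0.67, from 1.66 ± 0.470 CPM (SD, n = 2) to 30.4 ± 6.15 CPM (SD, n = 3). Per3 had 2.65 ± 0.63 and Tef 1.91 ± 0.42, from 51.5 ± 0.648 to 193 ± 47.4 CPM. For each of these 3 genes all 3 exposed livers lay above both controls. In edgeR no single gene passed the threshold, with the smallest adjusted p, 0.346, for Dbp and 316 genes at an unadjusted p under 0.05, while DESeq2 passed 7 genes, these 3 among them, and limma voom with library weights passed 3, Tef among them.

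Of 18 clock-list genes 13 were higher at 9 months (median 0.96, also with Npas2 at its bound) and the list rose as a set (camera adjusted p = 4.22e-08, adjusted p = 0.344 with an estimated correlation). It passed camera with each of the 10 libraries left out (highest adjusted p 0.000622). Adjusted over the list alone 7 were higher, Per2, Per3, Cry2, Nr1d2, Dbp, Tef and Ciart, and 2 lower, Arntl and Npas2. Over all genes 0 of the list passed in edgeR, Dbp, Per3, Tef and Nr1d2 passed in DESeq2, and Tef and Nr1d2 in limma voom with library weights. Nr1d2 had a log2 fold change of 1.48 ± 0.32, Per2 of 2.24 ± 0.75 and Arntl of -2.34 ± 0.83, from 18.2 ± 7.87 to 3.53 ± 2.34 CPM. Npas2, which can stand in for Clock as partner of the Arntl product, had 51 counts in the controls and 0 in the exposed livers and was at least 7.75-fold lower. The test of the difference between the times passed 1 gene adjusted over the list alone, Per3 (-6.13 ± 1.24), and the clock list did not pass as a set (adjusted p = 0.911, with a median of 0.31 and a mean of -0.63).

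**Figure D3:**
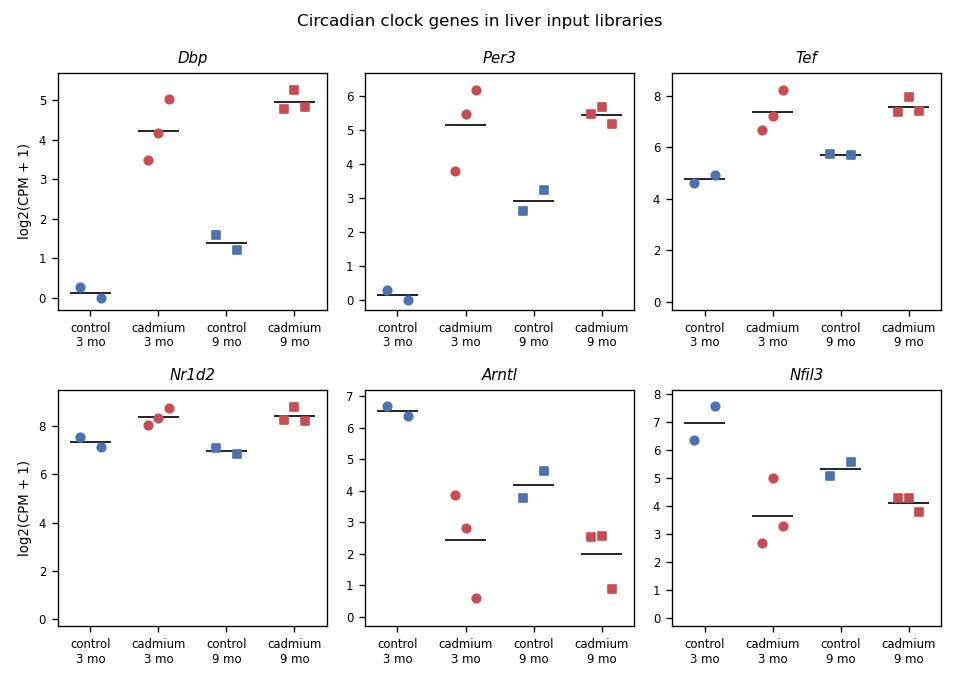
Abundance as log2(CPM + 1) on the y axes of the clock genes Dbp, Per3, Tef, Nr1d2, Arntl and Nfil3 in the control (blue) and exposed (red) livers of each time, each point a library and each line a group mean. In the exposed livers Dbp lies at 10.2 CPM or more at 3 months and at 26.4 CPM or more at 9 months, against 1.99 CPM or less in the controls.

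Camera also called 5 other lists at 9 months. The immediate early list, transcription factor genes induced within minutes of a stimulus, fell (median -0.96, 2 of 13 higher, adjusted p = 7.44e-07, adjusted p = 0.549 with an estimated correlation). Fos had a log2 fold change of -2.92 ± 0.84, Jun of -1.07 ± 0.40 and Egr1 of -1.49 ± 0.61, and Fos read 70.3 and 4.24 CPM in the controls. Cholesterol synthesis rose (median 0.69, 18 of 23 higher, adjusted p = 0.000846, adjusted p = 0.71 with an estimated correlation). So did the markers of Kupffer cells, the macrophages of the liver (median 0.43, 15 of 18 higher, adjusted p = 0.0137, adjusted p = 0.549 with an estimated correlation), with C1qb at 1.43 ± 0.66. The male-biased list rose (median 0.42, 14 of 18 higher, adjusted p = 0.0279, adjusted p = 0.642 with an estimated correlation), with the pheromone-carrier gene Mup20 at 1.45 ± 0.66 and the oxysterol hydroxylase gene Cyp7b1 at 1.21 ± 0.51. The pancreas list fell (median -2.88, 0 of 11 higher, adjusted p = 0.000846, adjusted p = 0.71 with an estimated correlation), beside the 9800 CPM of its genes in 9-month control 2. Of these 5 lists 0 members passed in edgeR over all genes or adjusted over the list alone, and with fry 0 lists passed (smallest adjusted p 0.844). The edgeR unadjusted p was under 0.05 for 4 of 13 immediate early, 0 of 23 cholesterol and 1 of 18 Kupffer cell genes. It was so for 3 of 18 male-biased and 1 of 11 pancreas genes. Members named here are examples, and not all follow the rule of highest level.

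In edgeR 0 of 14067 genes passed at 9 months, 316 had an unadjusted p under 0.05, and DESeq2 gave 7 and limma voom with library weights 3, with non-overlapping groups for 22% of genes where chance gives 20%. The fit without the low-count filter gave 76 genes, and the 5 libraries of that time alone gave Dbp (adjusted p = 0.0107, within a range of 2.84e-07 to 1.0 over its alternatives). Dbp also passed in edgeR without 3-month control 2 (0.0129) and without 3-month control 3 (0.0162). Outside the lists above, Cdkn1a was lower adjusted over the p53 list alone (-4.00 ± 0.91), from 33 ± 11.6 to 2.14 ± 2.64 CPM, with 0 of 18 over all genes in edgeR, though Cdkn1a was among the DESeq2 calls. Single libraries ended list calls at this time. The immediate early call was lost without 9-month control 1 and the cholesterol call without 9-month control 1 or exposed liver 2. The Kupffer cell call was lost without 9-month control 1, control 2 or exposed liver 1, the male-biased call without control 2 or exposed liver 2, and the pancreas call without control 2 or exposed livers 2 or 3 (highest adjusted p 0.167, 0.167, 0.139, 0.876 and 0.112). The number of list calls was 3 without 9-month exposed liver 2 and 6 without the 2 libraries with the most pancreas-list RNA, of which 3 were among the 6 called with all libraries.

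The third comparison asks whether the cadmium effect differed between 9 and 3 months. In edgeR 0 genes passed the threshold over all genes. Igfbp1 had a difference of 5.09 ± 1.16 on the log2 scale (adjusted p = 0.418). Genes of the glucose list past the threshold adjusted over the list alone included G6pc, Igfbp1, Foxo1 and Tat, with higher values of the effect at 9 than at 3 months, and Pklr, with a lower one, while the list did not pass camera (adjusted p = 0.236). Further genes past the threshold over their list alone were Gstm4 (-2.33 ± 0.52) of the NRF2 list, Mup20 (3.33 ± 0.91) and Cyp7b1 (2.31 ± 0.70) of the male-biased list, Acot3 (-4.37 ± 0.93) of the female-biased list, Pcna (1.63 ± 0.47) of the cell cycle list and Fos (-4.63 ± 1.30) of the immediate early list, with Tgfb1 of the cytokine list lower as well.

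As sets, 5 lists differed in camera between the times. Acute phase genes (median difference 0.90, adjusted p = 0.000983), the male-biased list (1.12, adjusted p = 0.00743) and ER stress genes (0.52, adjusted p = 0.0405) differed upward. PPARA targets (-0.62, adjusted p = 0.00742) and NRF2 and glutathione genes (-0.53, adjusted p = 0.0483) differed downward. Each of the 5 had adjusted p = 0.684 with an estimated correlation and was lost without 3-month control 3. With each library left out in turn, the call was kept in 8 of 10 fits for acute phase and PPARA genes, 7 for the male-biased list, 6 for ER stress and 3 for NRF2 genes. The number of these calls was 1 without 3-month exposed liver 1, 3 without 9-month control 1 and 3 without 9-month exposed liver 1. At 3 months alone NRF2 genes had a median of 0.16 (adjusted p = 0.0686, 4 of 25 higher adjusted over the list alone, Gstm4, Gpx1, Gpx4 and Ephx1) and at 9 months -0.14 (adjusted p = 0.23), and ER stress genes had -0.60 (0.0609) and 0.19 (0.259). In edgeR 1325 genes had an unadjusted p under 0.05, DESeq2 gave 40 genes and limma voom with library weights 0. The edgeR count was 321 without 3-month control 2 and 587 without 3-month control 3. Across all genes the effects at 3 and at 9 months had a Pearson r of 0.029 and a Spearman rho of -0.025, with the same sign in 46.9% of genes, which are not independent replicates.

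The fourth comparison sets the 2 control livers of 9 months against the 2 of 3 months. Pklr, a gene of glucose use, rose by 2.45 ± 0.45 on the log2 scale, from 23.5 ± 4.90 to 128 ± 2.76 CPM (SD, n = 2 and 2, edgeR adjusted p = 0.0307). Igfbp1 fell by 4.63 ± 0.97 (adjusted p = 0.0378), and Mup20, a male-biased urinary protein gene, fell by 3.43 ± 0.75 (0.0421). The immediate early genes Fos, Jun and Ier2 rose by 5.11 ± 1.11, 2.56 ± 0.48 and 3.09 ± 0.61, with Fos at 70.3 CPM in 9-month control 1 and 4.24 CPM in control 2. Per3 rose, with 1 count at 3 and 86 counts at 9 months, a ratio of 94.6 (exact 95% counting interval 16.5 to 3780). Ythdf3, which encodes a reader of m6A, fell by 1.61 ± 0.31, from 295 ± 79.3 to 96.5 ± 11.8 CPM (adjusted p = 0.0307).

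In edgeR 266 genes passed between the control groups, 131 higher and 135 lower at 9 months, and 2825 had an unadjusted p under 0.05. Of the list members that passed, Ftl1 (1.81 ± 0.42), Gstm4 (2.07 ± 0.41), the epoxide hydrolase gene Ephx1 (1.68 ± 0.38), the lipid droplet genes Cideb (1.41 ± 0.33) and Fitm1 (2.92 ± 0.69) and the bile acid regulator gene Nr0b2 (2.81 ± 0.55) rose. Tfrc (-1.88 ± 0.42), the chaperone gene Hsp90b1 (-1.31 ± 0.30) and the Y-linked gene Ddx3y (-1.65 ± 0.34) fell. With 0 counts in both 3-month controls, Taf5 was at least 14.2-fold, Plekhf1 at least 14.1-fold and Fam188b at least 8.18-fold higher. Likewise Tgfb1 was at least 8-fold and Slc2a5, a fructose transporter gene, at least 7.77-fold higher. Of these genes the 3-month exposed livers had 104, 86, 91, 68 and 103 counts, in that order. This comparison and that of cadmium at 3 months use the same 2 outlying 3-month controls. A change seen in both, as for Igfbp1, may therefore rest on those libraries. Tnfrsf26 had 0 counts in both 9-month controls and was at least 23.7-fold lower, and Fam134b (-4.36 ± 0.88), Nrg4 (-4.18 ± 0.96) and Arl15 (-3.78 ± 0.80) completed the 5 largest falls with Igfbp1. Groups did not overlap for 46.2% of genes, where chance gives 33.3%.

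The count between the control groups moved with each library left out. It was 991 and 2339 without 3-month control 2 or 3, 3 and 4 without 9-month control 1 or 2, 34, 1 and 104 without exposed liver 1, 2 or 3 of 3 months, and 14, 114 and 20 without exposed liver 1, 2 or 3 of 9 months. DESeq2 gave 1238 genes, and counts summed over transcripts and limma voom with library weights gave 0 each. Without the 2 libraries with the most pancreas-list RNA 1 gene passed. No list passed camera (smallest adjusted p 0.0942 for immediate early, median 1.25, and 0.141 for NRF2, median 0.73), and all had adjusted p of 0.836 or more with an estimated correlation. Adjusted over the list alone, 5 immediate early genes were higher and 1 lower (3 higher over all genes), 7 NRF2 genes were higher and 1 lower (2 higher over all genes), and 2 m6A machinery genes, Ythdf3 and Wtap, were lower (1 over all genes). Wtap had a log2 fold change of -1.31 ± 0.34 (adjusted p = 0.0596 over all genes). The pancreas list had a median of 5.11 with 11 of 11 higher (adjusted p = 0.225). With fry the list of Y-linked genes and Xist passed (adjusted p = 0.0373). Camera called 3 lists without 9-month control 1 or 2 and 1 list without 3-month control 2 or 9-month exposed liver 1 or 3.

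The last comparison sets exposed livers of 9 months against those of 3 months, with 3 livers each. In this comparison and the fourth, a possible batch cannot be told from time. Alyref, an mRNA export adaptor gene chosen after its values were seen, had the smallest p, with a log2 fold change of -2.31 ± 0.33 from 25.9 ± 3.27 to 5.22 ± 0.434 CPM (adjusted p = 0.0915). In the controls it read 44.9 ± 5.42 and 7.83 ± 0.191 CPM and passed the threshold (-2.52 ± 0.40, adjusted p = 0.0272). Saa1, an acute phase gene, had 4.90 ± 0.78 from 2.21 ± 1.25 to 67.1 ± 46 CPM (adjusted p = 0.151), and it passed adjusted over its list alone. In edgeR 0 of 14067 genes passed and 697 had an unadjusted p under 0.05, DESeq2 gave 17 and limma voom with library weights 3. Without 3-month control 2 or 3 the edgeR count was 11 or 10, and without 9-month control 1 or exposed liver 3 it was 1. Groups did not overlap for 14% of genes, where chance gives 10%.

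Camera called 9 lists in the exposed livers over time. PPARA targets fell (median -0.41, 6 of 25 higher, adjusted p = 0.000139, adjusted p = 0.545 with an estimated correlation), with the fatty acid hydroxylase genes Cyp4a10 (-2.56 ± 0.55), Cyp4a14 (-3.48 ± 0.81) and Cyp4a31 (-3.06 ± 0.86) lower adjusted over the list alone. Glucose metabolism rose (median 0.40, 13 of 16 higher, adjusted p = 0.000693, adjusted p = 0.418 with an estimated correlation), with G6pc (1.85 ± 0.37), Pck1 (1.23 ± 0.39) and Pygl (0.84 ± 0.27) higher over the list alone. ER stress genes rose (median 0.44, 14 of 20 higher, adjusted p = 0.000693, adjusted p = 0.545 with an estimated correlation), with the chaperone genes Manf (2.17 ± 0.63), Calr (1.04 ± 0.29) and Pdia4 (0.90 ± 0.26) higher over the list alone. Acute phase (median 0.47, adjusted p = 0.00234), cell cycle (0.55, adjusted p = 0.0322) and Kupffer cell genes (0.32, adjusted p = 0.0317) rose, with 1, 0 and 0 members past the threshold adjusted over the list alone. These 3 had adjusted p = 0.545, 0.509 and 0.545 with an estimated correlation. The female-biased list fell (median -1.02, 1 of 4 higher, adjusted p = 0.0115), with Fmo2 and Acot3 lower over the list alone, and the list of Y-linked genes and Xist fell (median -0.53, 0 of 5 higher, adjusted p = 0.000693). These had adjusted p = 0.418 and 0.235 with an estimated correlation. Xist, the RNA that silences an X chromosome, had 91 counts in the exposed livers of 3 months and 0 in those of 9 months, at least 8.01-fold lower, and was the 1 member lower over the list alone. The pancreas list rose (median 8.73, also with Try4 at its bound, 11 of 11 higher and past the threshold adjusted over the list alone, adjusted p = 0.000139, adjusted p = 0.545 with an estimated correlation), beside the 1900 CPM of its genes in 9-month exposed liver 1. Over all genes 0 members of these 9 lists passed in edgeR.

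Of these 9 lists, with fry only Y-linked genes and Xist passed (adjusted p = 0.00812). ER stress and the list of Y-linked genes and Xist passed camera with each of the 10 libraries left out (highest adjusted p 0.02 and 0.00719). PPARA targets and glucose metabolism lost the call without 3-month exposed liver 1 (0.0959 and 0.0562), and acute phase and pancreas genes lost it without 9-month exposed liver 1 (0.0831 and 0.588). Cell cycle lost it without exposed liver 1 or 3 of 3 months or 2 or 3 of 9 months, the female-biased list without 3-month control 2, 9-month control 1 or 9-month exposed liver 2 or 3, and Kupffer cell genes without 3-month control 2 or exposed liver 1 or 3 of either time (highest 0.115, 0.154 and 0.381). The number of list calls was 14 without 3-month exposed liver 3, 6 without 3-month exposed liver 1 and 6 without 9-month exposed liver 3.

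The remaining lists did not pass camera for cadmium at 3 or 9 months. Fatty acid and triglyceride synthesis had medians of 0.23 at 3 months (adjusted p = 0.0686) and 0.02 at 9 months (0.808), and adjusted over the list alone Srebf1 (2.39 ± 0.71), Fasn (1.11 ± 0.36), Fads2 (0.98 ± 0.29) and Dgat2 (1.01 ± 0.31), genes of lipid synthesis, were higher at 3 months, with 0 over all genes in edgeR. Fat uptake and lipid droplet genes had medians of 0.30 (0.39) and -0.34 (0.0917). Bile acid genes had -0.02 (0.739) and -0.15 (0.808), with Abcc3 and Nr0b2 higher and Cyp2c70 lower over the list alone at 3 months. Xenobiotic P450 genes had 0.04 (0.956) and -0.03 (0.854), heat shock genes 0.31 (0.179) and 0.11 (0.854), with Hsph1 higher over the list alone at 3 months, and autophagy genes -0.35 (0.537) and 0.03 (0.868). Cell cycle genes had 0.84 (0.739) and 0.52 (0.0538), with the camera direction down at 3 months against a median above 0 and Top2a and Pcna lower over the list alone. Cytokines and chemokines had 0.37 (0.515) and -0.08 (0.527), with Tgfb1 at least 6.4-fold higher at 3 months and past the threshold over the list alone. Extracellular matrix genes had -0.03 (0.547) and -0.10 (0.23). The camera direction also differed from the median's sign for immediate early, Y-linked and lymphocyte genes at 3 months and for heat shock, autophagy, Y-linked, female-biased and xenobiotic genes at 9 months. The mean and median differed in sign for m6A machinery, immediate early, Y-linked, Kupffer cell and endothelial genes at 3 months and for heat shock, autophagy, female-biased, Y-linked and endothelial genes at 9 months.

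Among cell type and sex lists, immediate early genes had a median of 0.04 at 3 months (adjusted p = 0.954), the male-biased list -0.59 (0.0609), Kupffer cell markers 0.14 (0.806), and PPARA targets, acute phase and interferon genes at 9 months had -0.15 (0.076), 0.09 (0.129) and 0 (0.512). The p53 list had -0.12 (0.129) and glucose metabolism 0.09 (0.854) at 9 months. The female-biased list, with 4 of 16 genes measured, had 0.16 (0.223) and -0.05 (0.868), with Acot3 higher over the list alone at 3 months (3.77 ± 0.74), and Y-linked genes and Xist had 0.16 (0.773) and 0.02 (0.808). Hepatocyte markers had -0.12 (0.287) and -0.12 (0.527), with Fgb and Tat lower over the list alone at 3 months. Endothelial markers had 0.13 (0.739) and 0.04 (0.818), cholangiocyte markers 0.03 (0.547) and 0.18 (0.854), with Krt23 higher over the list alone at 3 months (4.07 ± 1.31), and erythroid markers 0.30 (0.671) and -0.34 (0.255). Lymphocyte markers, with 5 of 19 genes measured, had 0.64 (0.29 with a gene at its bound, 0.956) and 0 (0.663), and neutrophil markers, with 3 of 10 measured, had 1.23 (1.20 with a gene at its bound, 0.634) and 1.30 (0.527). Of 7 adipose markers 1, Fabp4, was measured, at 3 and 39 counts at 3 months (ratio 7.97, exact 95% interval 2.53 to 40.3) and a log2 fold change of -0.46 at 9 months, too few for camera. Mitochondrially encoded mRNAs were not analysed here.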

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

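The list tests of the difference between times, with the estimated correlation and the left-out libraries, were chosen after the data were seen. A test of the difference between the cadmium effects at 9 and 3 months singled out 5 gene lists by camera. NRF2 and glutathione genes had a median of 0.16 at 3 months and -0.14 at 9 months, and the difference had an adjusted p of 0.0483. PPARA targets and fatty acid oxidation had 0.66 and -0.15 (adjusted p 0.00742). ER stress genes had -0.60 and 0.19 (adjusted p 0.0405), acute phase genes -1.05 and 0.09 (adjusted p 0.000983), and male-biased liver genes -0.59 and 0.42 (adjusted p 0.00743). The difference went the way of its median in 17 of 25 NRF2, 20 of 25 PPARA, 14 of 20 ER stress, 17 of 20 acute phase and 13 of 18 male-biased genes. Members tend to go the way of their own median by definition, and camera picked these lists from the same differences. The counts therefore add no support. With an estimated correlation each of the 5 had an adjusted p of 0.684, and without 3-month control 3 none passed camera, with the smallest adjusted p at 0.198. With each library left out in turn, NRF2 genes kept the call in 3 of 10 fits, ER stress genes in 6, male-biased genes in 7, and PPARA and acute phase genes in 8 each.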

How the results depend on the processing

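The tests with counts summed over transcripts, with limma voom and library weights, and without the pancreas-rich libraries or both 3-month controls, and the list tests of the difference, of time and with a library left out, were chosen after the result was seen. No named gene past the threshold reversed its direction against the edgeR fit of all 10 libraries. Mt1, Mt2 and Mettl3, not past the threshold at 3 months in that fit, changed sign at that time in some alternatives. Of the single-gene values 743 stayed on their side of the threshold, 307 lost the call and 39 gained it. The cause was not tested. Fewer samples leave fewer degrees of freedom, yet the counts at 3 months and between control groups rose when a 3-month control was left out.

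For cadmium at 3 months, against 7 genes, an adjusted p under 0.1 gave 113, DESeq2 479, no filter 502, the libraries of that time alone 0, summed counts 11 and limma voom with weights 2. At 9 months, against 0, DESeq2 gave 7, no filter 76, that time alone 1, limma voom 3 and the fit without both 3-month controls 1. For the difference, against 0, DESeq2 gave 40 and no filter 208. Between control groups, against 266, an adjusted p under 0.1 gave 953, DESeq2 1238, no filter 1073, at least 5 CPM 435, summed counts 0, limma voom 0 and the fit without pancreas-rich libraries 1. Between exposed groups, against 0, an adjusted p under 0.1 gave 1, DESeq2 17, no filter 96, limma voom 3 and the fit without both 3-month controls 6. With each library left out the counts ran from 3 to 1247, 0 to 1, 0 to 587, 1 to 2339 and 0 to 11 in these 5 comparisons.

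Of lists by camera, 7 passed at 3 months, 6 at 9 months, 5 for the difference and 9 between exposed groups. An estimated correlation gave 0 in each, and fry 0, 0, 0 and 1. At 3 months the estimate was 0.926 for pancreas, 0.611 for cholesterol synthesis, 0.591 for PPARA targets and 0.308 for acute phase genes. It was 0.16 for the clock list, 0.15 for interferon genes and 0.006 for the p53 list. Where the estimate lies above the preset 0.01, the camera p at the preset may be too small. Between control groups, against 0 lists, fry gave 1 and the fit without pancreas-rich libraries 3. With each library left out the lists ran from 0 to 10, 3 to 9, 0 to 7, 0 to 3 (control groups) and 6 to 14 (exposed groups).

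With the replicate number as a replicate block, 3 genes passed at 3 months, 2 of them among the 7, and 1 at 9 months, 0 for the difference, and 5, 6 and 4 lists. Deviations of same-numbered livers from their group means correlated across genes at 0.051 and 0.003 at 3 months and -0.34 and -0.119 at 9 months. The 2 controls of a time deviate from their mean in exactly opposite ways. With any 1 exposed liver they therefore give opposite values, as -0.34 and 0.34 with 9-month exposed liver 1. These values therefore cannot decide whether the numbers pair the livers. The planned m6A enrichment and peak results, with their alternatives, were not run, nor was a pseudocount, which counts do not need. Depth limits genes under 0.34 to 0.76 CPM, the floor of 3 counts.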

Other observations

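The tests of the clock score, of pancreas RNA among the control genes and of a label swap were chosen after the result was seen. For chance among the clock genes, for a swap and for noise of the 3-month controls, the condition to decide was made stricter after the values were seen, which left each open by its own test. Under the earlier conditions the values went against chance and a swap and pointed to noise. The earlier condition for noise, written beforehand, asked for far fewer calls with library weights in limma voom than with equal weights. The counts were 0 and 248. Between the control groups, further lists had members past the threshold adjusted over the list alone. The lipid synthesis genes Srebf1 (log2 fold change 2.44 ± 0.75), Fasn (1.5 ± 0.39) and Dgat2 (1.24 ± 0.33) were higher at 9 months, as were the haemoglobin genes Hba-a1 (3.24 ± 1.01) and Hbb-bs (1.75 ± 0.56) and the glutathione genes Gstm1 (1.33 ± 0.35), Gpx1 (0.87 ± 0.28) and Gpx4 (0.96 ± 0.30). The p53 targets Trp53inp1 (-2.10 ± 0.54) and Sesn1 (-2.67 ± 0.66) were lower. Over all genes none of these 10 passed in edgeR, with adjusted p from 0.0547 for Sesn1 to 0.108 for Hbb-bs, and each has an unadjusted p under 0.05. Srebf1, Fasn, Dgat2, Gpx1, Gpx4, Trp53inp1 and Sesn1 had the same direction for cadmium at 3 months, a comparison with the same 3-month controls.

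Clock genes lay apart between exposed and control livers at both times. A score of 11 genes that the clock activates minus 4 opposite ones ran from -3.06 to -1.19 in the 4 controls and from 0.24 to 2.84 in the 6 exposed livers. Of 100 rearrangements of the libraries within times 1, the real one, gave a summed difference as large, but the score was built after the arms were seen to separate, so a chance arrangement stays open. Without the 2 libraries rich in pancreas RNA the difference at 9 months was 3.55, which argues against that tissue as the cause. The difference was 4.17 at 3 months and 3.46 at 9 months, at least 3.38 and 3.32 with any library left out. A different hour of day at dissection and a clock shifted by cadmium may each give such a difference and cannot be told apart here, since both predict the same direction and the hour of sampling is not given in the sources used here.

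Between the control groups 266 genes passed in edgeR, and 248 in limma voom with equal library weights. With estimated weights, 0.32 and 0.44 for the 3-month controls and 0.8 or more for the others, 0 passed (smallest adjusted p 0.0546, 1690 at an unadjusted p under 0.05), as the median standard error of the 266 rose from 0.39 to 0.46 while their median change went from 1.83 (quartiles 1.56 and 2.43) to 1.80 (1.51 and 2.38) in the direction of the call. Without 3-month control 2 or 3 the count rose to 991 or 2339, with 227 or 261 of the 266 among them, and noise of these 2 libraries stays open, since a lone control is assumed to vary like the other groups. Without the 2 libraries rich in pancreas RNA the 266 kept a median share of 0.95 of their change (quartiles 0.87 and 1.02). Their median change went from 1.84 (1.55 and 2.51) to 1.71 (1.40 and 2.39), so it did not rest on those libraries. The 266 were called with both 9-month controls, where a gene raised in 1 control alone has a large spread and is less readily called. The selection thus favours a high share, and the test does not decide on pancreas tissue in a 9-month control as the cause. Age, time on study and a possible batch of each time cannot be told apart here and stay open as untested.

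Metallothionein was highest in 3-month control 3. The highest correlation of that library with an exposed one was 0.837, below the lowest among exposed livers of one time, 0.908, and above the 0.775 with its own control partner. It stands apart from every library, so the correlations leave a label swap open. Its clock score was -3.06, beside -2.79 in its control partner, while the exposed livers ran from 0.24 to 2.84. That library thus scored near its partner and below every exposed liver. The score was built after the arms, this library included, were seen to separate, so it cannot decide on a swap. Of 6 glucocorticoid-type genes 5 were highest in that library, Ddit4 at 329 CPM against at most 11.4 CPM elsewhere, Zbtb16 at 138 against 52.3, Sgk1 at 142 against 78, Fkbp5 at 280 against 188 and Klf9 at 191 against 155. Tsc22d3 was highest in 9-month exposed liver 2, at 125 CPM against 74. A glucocorticoid-type response in that animal is a candidate explanation, and no biological group in the design separates it from its partner. How many of all genes were highest in that outlying library was not counted, so the 5 of 6 have no baseline.

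Between 9 and 3 months in exposed livers 0 genes passed in edgeR, with 697 at an unadjusted p under 0.05, 17 by DESeq2 and 3 by limma voom with library weights. The 10 splits of these 6 libraries are too few for a share under 0.05, with 0 genes in the real split and a highest count of 0 in the others.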
